A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

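The series profiled messenger RNA of budding yeast (Saccharomyces cerevisiae) lacking LOC1 against wild type on 4 microarrays of 2 colours. On each array one channel held RNA of the knockout and the other held RNA of wild-type cells. Per the labels, the 4 arrays were biological replicates carried through separately, 2 with the knockout in Cy5 (replicates 1 and 4) and 2 with the knockout in Cy3 (replicates 2 and 3). Cultures of 50 mL in rich medium were taken in early log phase (optical density 0.2 to 0.4) at 30 °C. RNA was isolated with hot phenol, copied with an oligo-dT primer and labelled by Klenow polymerase with random primers, per the labels' protocols. The strain tag of the wild-type channel of replicate 4 names the knockout strain, while its source description names wild type; the description was followed.

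The values used were the authors' deposited log ratios, 1 per gene and array, in a table of 6210 rows. The scanner, the background correction, the normalization and the log base are not given in the sources used here. The deposited values were taken as log10 ratios, from the values alone. They end exactly at a size of 2, which 22 values in 17 genes reached, and the largest size below that limit was 1.41. A size of 2 is a ratio of 100 in base 10 and of 4 in base 2. Values are therefore given in deposited log units, and folds are given "if base 10". The tests do not depend on the base, except for the count with a fold requirement. The medians of the deposited columns were 0.007, -0.0107, 0.0012 and 0.0119 on arrays 1 to 4, so the columns were close to centred, and no further centring was applied in the main setting. Single spots and their intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

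The direction of the ratios was not settled by the dyes. If the table held Cy5 over Cy3, arrays of the same labelled orientation would run the same way and arrays of opposite orientation would oppose each other, and a table already turned to one direction would have all 4 arrays running the same way. Neither held. The rule written before the data were examined chose between these cases by the correlations between arrays and the LOC1 row. It took the overall sign from the dyes, with LOC1 as a check, and did not provide for this outcome. After the values were seen, arrays 2 and 4 were turned to place LOC1 below 0 on every array. This alignment rests on measured values, and the direction is called likely. All values below are knockout over wild type under this alignment.

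Rows of 3 controls were left out, which left 6207 gene rows. Gene names came from a RefSeq gene table of the assembly R64, matched on locus tags: 5654 of the IDs matched, 553 did not, and 5129 rows had a symbol other than the ID. The table was used for names and for which genes neighbour each other, and no coordinates are given because the array's probe positions and genome build are not given in the sources used here. Probe sequences were not used here, so genes with near-identical copies (PHO11 and PHO12, the AAD family, paired ribosomal protein genes, histone genes, hexose transporters and transposon rows) may share signal.

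A gene was tested where at least 3 of the 4 arrays had a value, which 6205 rows had and 2 did not. The test was lmFit and eBayes of limma 3.58.1 in R 4.3.3, 1 mean per gene against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It was tested on simulated data of 6192 genes with 200 changed. It recovered 22% of the genes changed by 0.1 log units, 90% of those changed by 0.2 and 100% of those changed by 0.3 or 0.5. Its calls held 5.45% unchanged genes, and it made 0 calls when no gene was changed. In the data 44.2% of the tested rows passed, so the adjustment was less strict there and genes near 0.1 could pass more often. The simulated genes were independent and no array signs were chosen, so the 0 calls do not describe the alignment used. An exact sign-flip permutation test of LOC1 was added.

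Before the data were examined, 37 gene lists were written from textbook knowledge, and 34 genes stand in more than 1 list. They were tested with camera of limma with a preset correlation of 0.01 over genes with a value on all 4 arrays, with Benjamini-Hochberg adjustment over the 37 lists. The test was repeated with an estimated correlation, which also leaves camera with the few residual degrees of freedom of 4 arrays. For each list the members past the threshold are given over all genes tested and adjusted over the list alone. Named genes followed a rule written before the data were examined. It took LOC1 and ASH1, the 10 largest rises and the 10 largest falls among genes past the threshold with a symbol and the same sign on every measured array, and up to 4 members of each described list with the largest changes past the threshold, or the 2 with the smallest p where fewer than 2 passed. Other genes are said to have been chosen after their values were seen.

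The alternatives were a dye term, median centring, scaling and quantile normalization between arrays, and other minimums of arrays with a value. Further ones were each replicate left out in turn, trended and robust eBayes, array weights and a fold requirement of 2. Arrays turned by the dye labels, an estimated correlation and fry were also used. The dye term took its signs from LOC1, and a term for the labelled dyes was not fitted. The trend of eBayes was fitted on the mean log ratio of each gene and not on intensity. The median over spots of a gene was planned too, and was not run because the table holds 1 value per gene and array.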

Results

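LOC1 encodes a nuclear RNA-binding protein that takes part in the assembly of the large ribosomal subunit and in the localization of ASH1 mRNA to the bud. The series asked how steady-state mRNA levels differ between yeast cells lacking LOC1 and wild-type cells in rich medium at 30 °C. Each of the 4 arrays compared 1 knockout culture with 1 wild-type culture directly, and the measurement is the log ratio of the channels. The arrays held between 6198 and 6207 values each for 6207 gene rows, and 17 values were missing in all. Of these rows, 6192 had a value on all 4 arrays.

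LOC1 had the lowest mean of all 6205 genes tested, at -1.14 ± 0.146 log units (SD, n = 4), or 13.7-fold lower if base 10 and 2.20-fold lower if base 2. As deposited, its values were -1.20, 0.972, -1.07 and 1.31 on arrays 1 to 4. With the knockout labelled Cy5 on arrays 1 and 4 and Cy3 on arrays 2 and 3, ratios of Cy5 over Cy3 would place LOC1 lower in the knockout on arrays 1 and 2 and higher on arrays 3 and 4, and ratios of Cy3 over Cy5 the reverse. Which of these the table holds is not given in the sources used here. The sign of LOC1 after turning was set by the alignment, so its size is the measurement. The limma adjusted p of 1.4e-05 and the exact sign-flip p of 0.125, two-sided and the smallest that 4 arrays allow, do not test its change, because the signs were chosen on LOC1. Whether the probe lies in the deleted part of the gene is not given in the sources used here.

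The other genes were aligned in the same way as LOC1. Across 6178 genes without LOC1, the deposited ratios of arrays 1 and 4, labelled with the same orientation, correlated at r = -0.773, and those of arrays 2 and 3, likewise of 1 labelled orientation, at r = -0.712. Arrays of opposite labelled orientation correlated at -0.763 (1 and 2), 0.758 (1 and 3), 0.653 (2 and 4) and -0.847 (3 and 4). These are correlations across genes, which are not independent replicates. The direction is therefore not settled by the dye labels, and "higher in the knockout" stands for the direction in which LOC1 is lower. With the sign turned, every rise and fall below exchanges: 1345 genes would be higher and 1398 lower, LOC1 would be the largest rise and HSP12 the largest fall. The turned sign would place the deleted gene far higher in cells labelled as lacking it, so it is the less likely one. With arrays turned by the dye labels instead, 1 gene passed the threshold in limma, and 72 had an unadjusted p under 0.05. Arrays 1 and 2 alone, where the dyes and LOC1 give 1 direction if the table holds Cy5 over Cy3, had 1185 genes past the threshold, of which 1126 were among the genes called on all 4 arrays with the same sign. Arrays 3 and 4 alone, where they do if it holds Cy3 over Cy5, had 2891, of which 2271 were.

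HSP12, which encodes a small stress-induced membrane protein, rose most, by 1.17 ± 0.183 log units (SD, n = 4, 14.9-fold if base 10). Among genes past the threshold, next came CHA1, the catabolic serine and threonine deaminase, at 0.863 ± 0.105 (7.30-fold if base 10), and the glycine decarboxylase subunits GCV1 at 0.542 ± 0.0544 and GCV3 at 0.523 ± 0.105. The deepest falls after LOC1 were in PHO12, a repressible acid phosphatase, at -0.911 ± 0.176 (8.14-fold lower if base 10), in PHO84, the high-affinity phosphate transporter, at -0.796 ± 0.274, and in AAD6, a putative aryl-alcohol dehydrogenase, at -0.758 ± 0.0693. In all, 2743 of 6205 genes (44.2%) passed the threshold, 1398 higher and 1345 lower in the knockout. Of these, 1355 of the higher and 1318 of the lower had the same sign on every measured array. Over all genes tested, 56.6% had the same sign on every measured array, a share that the alignment of the arrays on these values partly builds in. Most changes were small: the median size over all genes was 0.0679 log units against a median SD between arrays of 0.0505. With a change of at least 2-fold if base 10, 150 genes passed, 52 higher and 98 lower.

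Among genes with a symbol, the other largest rises were those of PNS1 at 0.522, the cell wall mannoprotein gene CWP1 at 0.485, the riboflavin synthesis gene RIB4 at 0.444, RTC3 at 0.433, the mitochondrial protein gene MMF1 at 0.431 and the histidine synthesis gene HIS5 at 0.401. Their SDs lay between 0.0323 and 0.0803 (n = 4) and their adjusted p values between 2.6e-05 and 6.6e-05 in limma. Among genes with a symbol, the other largest falls were those of the acid phosphatase gene PHO11 at -0.648, the peptide transporter gene PTR2 at -0.607, the polyphosphate synthesis genes VTC3 at -0.594 and VTC4 at -0.529, AAD15 at -0.583 and the glutathione transferase gene GTT2 at -0.545. Their SDs ran from 0.0572 for GTT2 to 0.351 for PTR2.

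**Figure D1:**
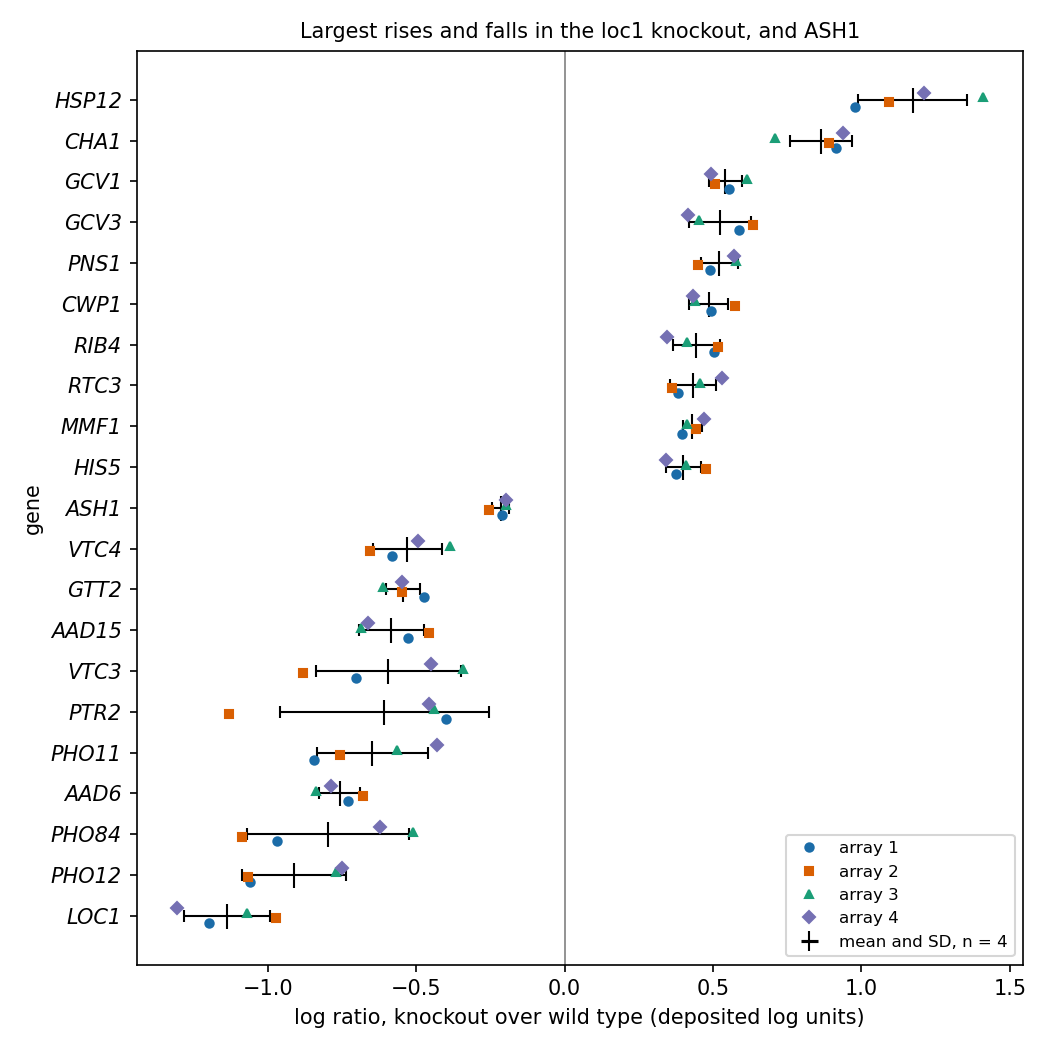
Log ratio of the knockout over wild type in deposited log units (x axis) for the 10 largest rises and 10 largest falls among genes with a symbol, and ASH1 (y axis). Symbols are the 4 arrays after alignment on LOC1, and bars are the mean and SD. HSP12 reached a mean of 1.17 and LOC1 a mean of -1.14. The rises and falls were chosen to have the same sign on every measured array, and ASH1 also had 1 sign on all 4 arrays.

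Genes for the ribosome and its assembly were higher in the knockout as groups by camera with the preset correlation. With an estimated correlation none of the 4 lists passed, at adjusted p = 0.616 to 0.686, and by the directional test of fry the assembly lists did not, at adjusted p = 0.133 and 0.0924. Among genes of large-subunit proteins, 39 of 77 rose and 2 fell (40 and 2 adjusted over the list alone), with RPL37B at 0.253 ± 0.0366 and RPL39 at 0.252 ± 0.0484 (SD, n = 4) the largest, followed by RPL43A at 0.247 and RPL28 at 0.216. The list's median was 0.0717, with adjusted p = 1.5e-05 by camera of limma and adjusted p = 0.616 with an estimated correlation. Among genes of small-subunit proteins, 26 of 56 rose and 3 fell (26 and 3 adjusted over the list alone), led by RPS27A at 0.264, RPS30B at 0.217, RPS29A at 0.199 and RPS9B at 0.195. Their median was 0.0685, with adjusted p = 0.00043 by camera and adjusted p = 0.616 with an estimated correlation. Of the factors that assemble the 60S subunit, in which Loc1 itself acts, 35 of 75 rose and 3 fell (36 and 4 adjusted over the list alone). MRT4 at 0.340, RRP15 at 0.288, NSA2 at 0.282 and RPF1 at 0.263 rose most. The list's median was 0.0769, with adjusted p = 0.00012 by camera and adjusted p = 0.686 with an estimated correlation. Of the factors of the 40S subunit and the processome of its precursor RNA, 31 of 66 rose and 2 fell (34 and 3 adjusted over the list alone), with IMP4 at 0.380, UTP9 at 0.303, PNO1 at 0.280 and UTP11 at 0.242. Their median was 0.0861, with adjusted p = 1.6e-05 by camera and adjusted p = 0.675 with an estimated correlation. On arrays 1 to 4 the medians were 0.134, 0.135, 0.0681 and 0.0029 for the 60S factors and 0.141, 0.128, 0.0659 and 0.006 for the 40S factors, so both lay near 0 on array 4. Translation factors were lower by camera, at adjusted p = 0.0077, and adjusted p = 0.616 with an estimated correlation. Of these genes, 17 of 38 fell and 1 rose (19 and 2 adjusted over the list alone), with TEF4 at -0.235, TIF4631 at -0.232 and FUN12 at -0.188, while TIF11 rose by 0.175. Their median was -0.0646, and adjusted p = 0.0544 on arrays 1 and 2 alone.

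The phosphate regulon was lower as a group by camera, at adjusted p = 3.6e-08, and adjusted p = 0.523 with an estimated correlation. Of its 20 measured genes 16 fell and 0 rose (18 and 0 adjusted over the list alone), and the list's median of -0.297 was the lowest of the 37 lists. Besides PHO12, PHO84, PHO11 and VTC3, the fallen members PHO5 at -0.516 and PHO8 at -0.239 encode phosphatases, and both were named after their values were seen. The list's median was -0.46 on array 1, -0.333 on array 2, -0.184 on array 3 and -0.203 on array 4.

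Genes of sugar use, protein folding and methionine synthesis were also lower by camera with the preset correlation, and none of these 5 lists passed with an estimated correlation (adjusted p = 0.354 to 0.523). In glycolysis and fermentation 19 of 27 fell and 2 rose (20 and 2 adjusted over the list alone). ADH1 at -0.351 ± 0.0183, PGK1 at -0.336 ± 0.0323, ENO2 at -0.326 and ADH2 at -0.323 fell most. ADH2 also stands in the list of galactose and other carbon use. The glycolysis list had adjusted p = 3.1e-06 by camera of limma and 0.354 with an estimated correlation. Of the hexose transporter genes, 8 of 19 fell and 1 rose, also adjusted over the list alone, with HXT3 at -0.288, HXT4 at -0.278, HXT5 at -0.244 and HXT2 at -0.216. Camera gave adjusted p = 0.039 for this list, adjusted p = 0.523 with an estimated correlation, adjusted p = 0.0667 without replicate 3, and adjusted p = 0.0559 on arrays 1 and 2 alone. Of the chaperone genes under the heat shock factor Hsf1, 17 of 26 fell and 3 rose (18 and 3 adjusted over the list alone), among them KAR2 at -0.394, SSC1 at -0.348, SSE1 at -0.329 and SSA1 at -0.319 (adjusted p = 4.2e-05, and adjusted p = 0.354 with an estimated correlation). Of the genes of the unfolded protein response of the endoplasmic reticulum, 13 of 20 fell and 2 rose (13 and 3 adjusted over the list alone), with ERO1 at -0.439, KAR2, PDI1 at -0.336 and OPI3 at -0.318. ERO1, KAR2 and PDI1 act in folding and disulfide formation, and OPI3 acts in phospholipid synthesis. This list had adjusted p = 0.0011, and adjusted p = 0.354 with an estimated correlation. In methionine synthesis and sulfate assimilation 15 of 26 fell and 2 rose (15 and 3 adjusted over the list alone), with SAH1 at -0.356, SAM2 at -0.297, MET6 at -0.296 and MET5 at -0.259 (adjusted p = 0.0011, and adjusted p = 0.363 with an estimated correlation).

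ASH1, which encodes a repressor of mating-type switching in daughter cells, fell by 0.215 ± 0.0282 log units (SD, n = 4, 1.64-fold if base 10), with adjusted p = 0.00034 in limma. Of the mRNAs known to travel to the bud, ASH1 among them, 12 of 23 fell and 3 rose, also adjusted over the list alone, with CPS1 at -0.375, EGT2 at -0.296, TCB2 at -0.254 and IST2 at -0.225. Camera gave adjusted p = 0.012, and adjusted p = 0.354 with an estimated correlation. Of the genes whose products carry or repress ASH1 mRNA, 6 of 11 fell and 1 rose, also adjusted over the list alone, and LOC1 is itself a member. The others named are SCP160 at -0.231, HEK2 at -0.190 and DHH1 at -0.184, all RNA-binding or RNA helicase genes. The remaining members were named after their values were seen. PAB1 at -0.145 and SHE3 at -0.0631 also fell, and PUF6 rose by 0.170. MYO4 at -0.0512, SHE2 at -0.0792, BNI1 at -0.052 and SHE4 at -0.0074 did not pass. The list had adjusted p = 0.0071, adjusted p = 0.033 without LOC1, and adjusted p = 0.354 with an estimated correlation. Of the genes expressed in daughter or in mother cells, 9 of 19 fell and 2 rose, also adjusted over the list alone, with EGT2, ASH1, AMN1 at -0.195 and SUN4 at -0.166. This list had adjusted p = 0.040 by camera and adjusted p = 0.523 with an estimated correlation. It did not pass without replicate 3 (adjusted p = 0.0553), without replicate 4 (adjusted p = 0.067) or on arrays 1 and 2 alone (adjusted p = 0.135).

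Among cell cycle and cell type lists, histone genes were higher: 8 of 11 rose and 0 fell, also adjusted over the list alone, with HHF2 at 0.262, HHF1 at 0.247, HTB2 at 0.214 and HHT2 at 0.209. The histone list had a median of 0.191, with adjusted p = 0.00064 by camera and adjusted p = 0.561 with an estimated correlation. Genes of the G2/M and M/G1 periods were lower, with 15 of 34 fallen and 1 risen (16 and 1 adjusted over the list alone). The members with the largest changes were the acid phosphatase gene PHO3 at -0.387, TEC1 at -0.245, BUD8 at -0.168 and, in the other direction, NCE102 at 0.341 (adjusted p = 0.0017, and adjusted p = 0.354 with an estimated correlation). Of the genes specific to MATa cells, 4 of 7 fell and 1 rose (5 and 1 adjusted over the list alone). BAR1, the protease that degrades alpha factor, fell by 0.497 ± 0.0649 log units, and STE6 and AGA2 had -0.136 and -0.125. MFA1 had -0.160 and lost its call without replicate 1 (-0.0937, adjusted p = 0.0816), 3 (-0.162, adjusted p = 0.0796) or 4 (-0.173, adjusted p = 0.0532). The list had adjusted p = 0.039 by camera, adjusted p = 0.464 with an estimated correlation, and adjusted p = 0.0517 without replicate 1. None of the 5 MATalpha-specific genes passed (0 and 0 adjusted over the list alone), with MF(ALPHA)1 at 0.0779 and SAG1 at 0.0184, and the list had adjusted p = 0.760, and 0.822 with an estimated correlation. Without replicate 3, MF(ALPHA)1 passed at 0.112 with adjusted p = 0.0278. In the list of mating and the pheromone response of haploid cells, 7 of 30 rose and 2 fell (6 and 2 adjusted over the list alone), with PRM10 at 0.383, STE12 at -0.219, PRM3 at 0.214 and AGA1 at -0.149. It had adjusted p = 0.291, and 0.620 with an estimated correlation. The list of meiosis and sporulation was higher by camera at adjusted p = 0.039, and adjusted p = 0.561 with an estimated correlation, with 14 of 37 risen and 4 fallen, also adjusted over the list alone. Its largest changes were mostly falls, in the glucan synthase gene GSC2 at -0.263, the meiotic activator IME1 at -0.262 and SPO11, which makes the meiotic DNA breaks, at -0.255, while SPO13 rose by 0.251. The list's median was 0.0737 on all 4 arrays. By camera it did not pass without replicate 3 (median 0.0741, adjusted p = 0.0563) or without replicate 4 (median 0.0501, adjusted p = 0.126). Nor did it pass on arrays 1 and 2 alone (median 0.0607, adjusted p = 0.327) or by the directional test of fry (adjusted p = 0.0673).

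The genes next to LOC1 and the usual auxotrophic markers were read as checks on the strains. Of the 5 neighbours of LOC1 in the list, DEG1 rose by 0.103 and the other 4 did not pass (1 and 0 adjusted over the list alone), with NIC96 at 0.0496. The list of neighbours had adjusted p = 0.291 by camera, and 0.686 with an estimated correlation. SAD1, a nearby gene outside the list and named after its value was seen, rose by 0.0769 (adjusted p = 0.0266 in limma). Of 8 auxotrophic marker genes, TRP1 at 0.311, HIS3 at 0.253 and URA3 at 0.155 rose and MET17 fell by 0.204 (3 and 1 adjusted over the list alone). URA3 lost its call without replicate 1, where it was at 0.141 with adjusted p = 0.0656 in limma. The list had adjusted p = 0.141, and 0.686 with an estimated correlation, and the strains' marker genotypes are not given in the sources used here.

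The other lists did not pass the threshold by camera of limma on all 4 arrays. On arrays 1 and 2 alone, 3 lists passed that did not on all 4, all higher: Gcn4 targets (adjusted p = 0.0021), RNA polymerase I and III (0.0094) and auxotrophic markers (0.0417). On arrays 3 and 4 alone, 2 more passed, both lower: mitochondrial ribosomal proteins (0.0035) and the nuclear pore and mRNA export (0.0443). The stress-induced list had 14 of 60 members higher and 15 lower, also adjusted over the list alone, with HSP12 at 1.17, DDR48 at -0.362, CYC7 at 0.292 and SPI1 at 0.280 (adjusted p = 0.796). The list of Gcn4 targets, mostly of amino acid synthesis, also holds GCN4 itself. It had 18 of 51 higher and 8 lower (20 and 10 adjusted over the list alone), with adjusted p = 0.0854. Its named members were HIS5 at 0.401, SNZ1 at 0.385, SER3 at -0.355 and LYS1 at 0.306. RNA polymerase I and III genes had 15 of 37 higher and 4 lower, also adjusted over the list alone, with RPC25 at 0.168, RPA34 at 0.163, RPC19 at 0.162 and RRN11 at 0.155 (adjusted p = 0.0591). For genes of snoRNP and rRNA modification the counts were 3 higher and 4 lower of 16 (adjusted p = 0.904), for the proteasome 8 and 6 of 35 (0.796), for ergosterol synthesis 4 and 6 of 26 (0.864) and for galactose and other carbon use 4 and 3 of 18 (0.864). All of these counts also held adjusted over the list alone. The respiratory chain and TCA cycle had 11 higher and 13 lower of 49 (11 and 14 adjusted over the list alone, adjusted p = 0.825), mitochondrial ribosomal proteins 2 and 13 of 63 (2 and 9, adjusted p = 0.212) and the iron regulon 7 and 9 of 30 (8 and 9, adjusted p = 0.819). Cell wall genes had 11 higher and 6 lower of 36 (adjusted p = 0.453), G1/S genes 5 and 10 of 33 (adjusted p = 0.252) and genes of fatty acid oxidation and the peroxisome 6 and 1 of 25 (adjusted p = 0.171), with the same counts adjusted over the list alone. Genes of the nuclear pore and mRNA export had 2 higher and 12 lower of 41 (2 and 11 adjusted over the list alone, adjusted p = 0.0668), and splicing factors had 9 and 4 of 43 (7 and 3, adjusted p = 0.291).

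**Figure D2:**
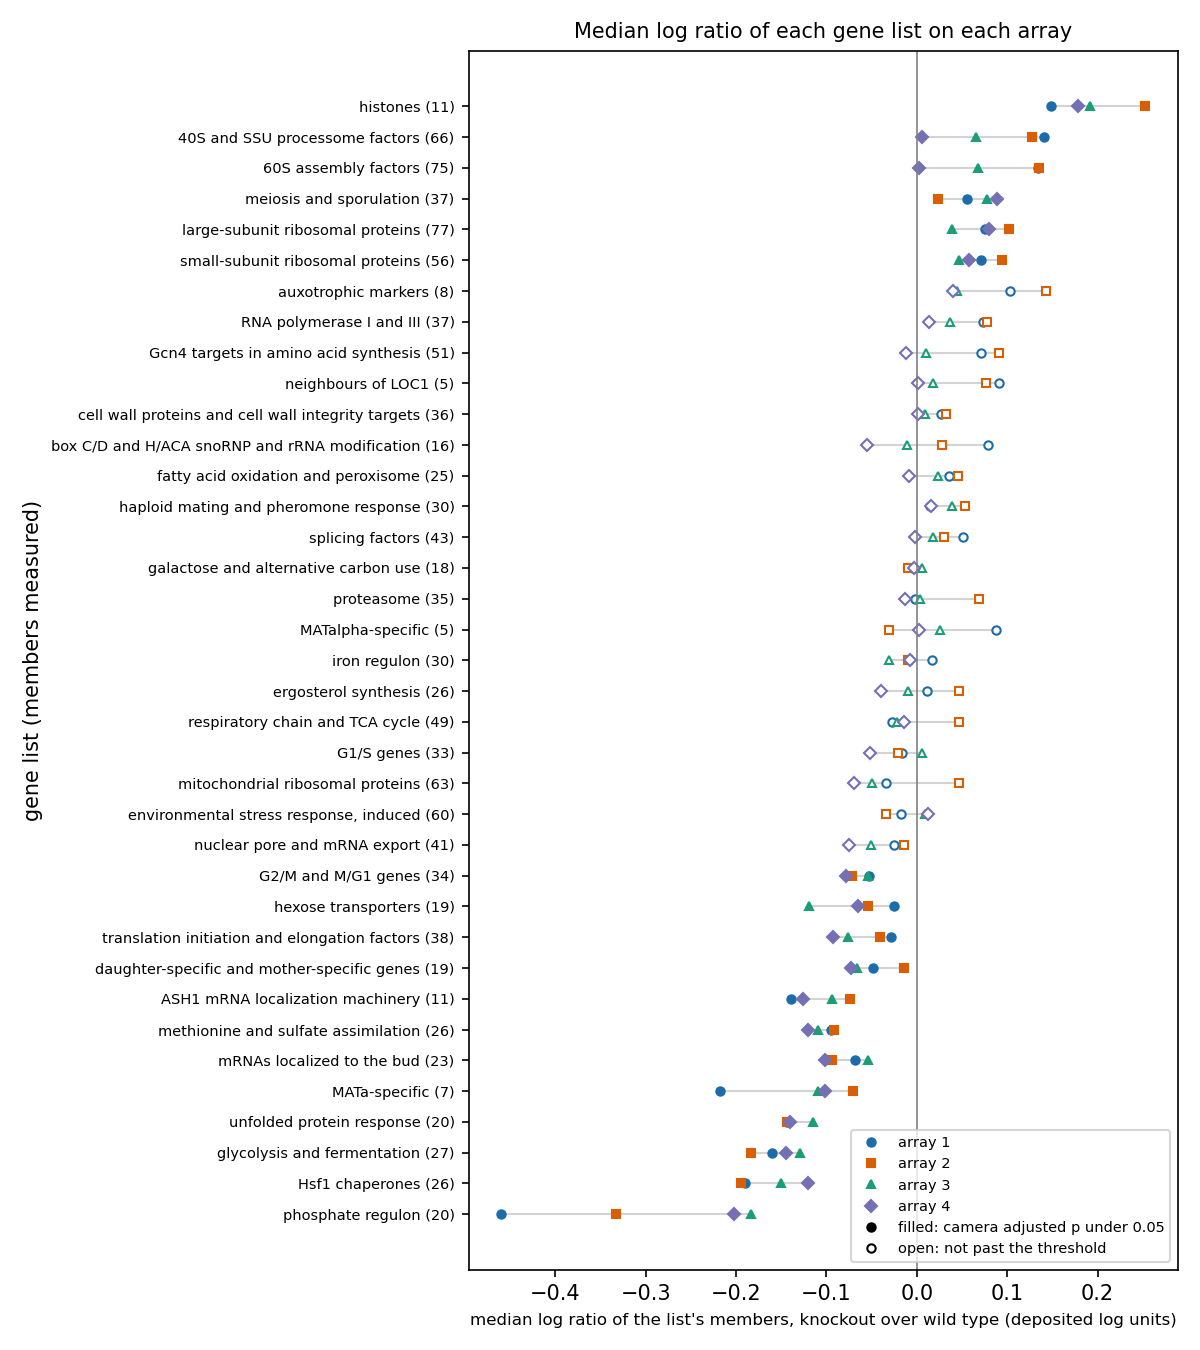
Median log ratio of the knockout over wild type in deposited log units (x axis) over the measured members of each of the 37 lists (y axis), for each of the 4 arrays after alignment on LOC1. Filled symbols mark the 18 lists past the threshold by camera with the preset correlation, whose medians had the same sign on all 4 arrays, from the phosphate regulon at -0.297 over the array means to the histones at 0.191.

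Of the 37 lists, 18 passed the threshold by camera with the preset correlation, 6 higher and 12 lower in the knockout, and 12 higher and 6 lower with the sign turned. With an estimated correlation 0 passed, and the smallest adjusted p was 0.354. That setting also leaves camera few residual degrees of freedom, so the loss of calls does not measure gene correlation alone. For glycolysis and fermentation the estimated correlation was -0.0082, and the unadjusted camera p still went from 1.7e-07 to 0.0098. For the phosphate regulon the estimated correlation was 0.607. By the directional test of fry, which asks whether a list moves one way and not whether it stands apart from other genes, 17 lists passed, 15 of them among the 18. The others were cell wall genes (fry adjusted p = 0.0195) and genes of fatty acid oxidation and the peroxisome (fry adjusted p = 0.0405).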

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

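The tests of dyes, labels, array pairs, stress genes and chromosome copy in this part were chosen after the results were seen. Of 176 results checked (137 genes, 37 lists and 2 summaries of the arrays), 7 had 1 array far from the other 3, and chance gives about 8.8. PTR2 was -1.13 on array 2 and between -0.456 and -0.399 on the others, so its mean of -0.607 would be -0.432 without array 2. BAR1 was -0.593 on array 4 against -0.474 to -0.457. OPI3 was -0.387 on array 3 against -0.303 to -0.291. AGA1 was -0.0918 on array 4 against -0.170 to -0.166. RPC25 was 0.270 on array 2 against 0.122 to 0.141. RIB2 was -0.0299 on array 2 against 0.0096 to 0.0125. The median of the unfolded protein response list was -0.115 on array 3 against -0.144 to -0.140.

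The pair of arrays 1 and 2 and the pair of arrays 3 and 4 opposed each other on the dye labels, in LOC1 and across genes. If LOC1 is lower in the knockout, arrays 3 and 4 run against their labels in a table of Cy5 over Cy3, and arrays 1 and 2 in a table of Cy3 over Cy5, which the sources used here do not give. A knockout culture in both channels of array 4, which 1 strain tag names, would leave a LOC1 ratio near 0. The measured size of 1.31 was the largest of the 4, against a smallest of 0.972. This size does not bear on an exchange of the channels of array 4, which the tag could also reflect. If no column was turned before deposit, a dye effect common to the arrays would lie in the mean of the columns as deposited. That mean had a median size of 0.0158 against 0.0678 for the aligned mean. If the labels hold, such an effect would lie in the aligned contrast of arrays 1 and 4 against 2 and 3, with a median size of 0.0178. The alignment was chosen on the opposition of the columns, so the larger size of the aligned mean was largely fixed by that choice. Exchanged dye labels on 1 of the pairs, or a table in which 1 pair alone had been turned, stay open. The spread expected to hold the dye effect under exchanged labels was 0.924 times that expected under the labels, and each rests on 1 contrast of 4 arrays that also holds differences between cultures. No biological explanation was tested.

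Arrays 3 and 4 resembled each other most, with a spread of differences of 0.0586, and arrays 1 and 2 came next at 0.0793. The smallest spread between arrays of different pairs was 1.04 times the larger within-pair spread, which leaves the pairing open. Other values go with a pairing: the contrast of arrays 1 and 2 against 3 and 4 had a spread of 0.0348, against 0.0235 and 0.0254 for the others, and the phosphate list's medians were -0.46 and -0.333 on arrays 1 and 2 against -0.184 and -0.203 on arrays 3 and 4. The aligned correlations go partly against it, with r = 0.773 across genes for arrays 1 and 4 against 0.763 for arrays 1 and 2. No label gives a batch, and 4 arrays are too few to tell. If the pairs were technical dye swaps, which the labels' biological replicates speak against, n would be 2. With the means of arrays 1 and 2 and of arrays 3 and 4 as 2 replicates, 2181 genes passed the threshold in limma, of which 2131 were among the 2743 with the same sign.

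HSP12 rose most, on all 4 arrays. A stress response of about its size across the list would raise the other members too, and the 59 others had a median of -0.0353 and an SD of 0.133 between members, with 13 higher and 15 lower, so a rise of at least 0.587 across the list is argued against. Extra copies of chromosome VI, which holds HSP12, would raise its 119 measured genes, and their median was 0.0039. Of the measured neighbours of HSP12, YFL015C at 0.219 and YFL012W at 0.110 rose, and MDJ1 at -0.166 and IES1 at -0.080 fell. The neighbours GNA1 and HXT10 did not pass. A weaker or partial stress response, a difference at HSP12 alone in the strain and a fault of the single HSP12 row stay open and were not tested.

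The count of 2743 genes was set against the other sign patterns of the 4 arrays. Of 8 patterns, 1 gave a count as large, the one used, and the highest of the others was 1. The pattern used was chosen from LOC1 and the correlations between these arrays, so its rank was fixed by that choice, and with 8 patterns no share under 0.05 can be reached.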

How the results depend on the processing

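The settings on arrays 1 and 2 or 3 and 4 alone, ratios as deposited, pair means, a pair term, values at the limit left out and lists without LOC1 were chosen after seeing the data. The count of 2743 genes lay between 2287 and 3003 under a dye term with the LOC1 signs, the 3 normalizations, the other minimums of arrays, trended and robust eBayes and array weights. It lay between 2009 and 2598 with 1 replicate left out. It was 3070 with a pair term, 2891 on arrays 3 and 4 alone and 2805 without values at the limit. It was 150 with a fold requirement of 2 if base 10, which is a stricter criterion, and 1185 on arrays 1 and 2 alone, of which the cause was not tested. It was 1 with arrays turned by the dye labels and 0 as deposited, where 1 gene had an unadjusted p under 0.05 in limma, because these sign patterns set arrays that oppose each other against one another. The mean of LOC1 ran from -1.30 to -1.08 under the settings chosen before the data were examined, other than the labels' signs. The 18 lists became 0 with an estimated correlation and 36 with the mixed test of fry, which asks another question, and 16 to 20 otherwise. Leaving out 1 replicate gave 16 to 19. For 107 named genes, 12 such settings other than the labels' signs gave 1284 values, of which 1278 kept direction and side of the threshold, 4 lost their call, 1 gained it and 1 changed sign without a call, SAG1, which ran from -0.0113 to 0.0349 with 1 replicate left out. The cause was not tested. Each ratio already pairs a knockout with a wild-type culture on 1 array, so no further block was fitted for that pairing. Signal over background is unknown, so its effect on dim genes could not be set apart.

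With arrays turned by the dye labels, 66 of the named genes kept their direction and lost the call, 3 had no call in either, and 38 changed sign with sizes from 0.0042 to 0.137 and no adjusted p under 0.9997. The signs of arrays 3 and 4 alone make this difference. These were LOC1 at 0.0518, HSP12 at -0.137, GCV1 at -0.0116, PNS1 at -0.0529, RTC3 at -0.0611, MMF1 at -0.0105, AAD6 at 0.0546, AAD15 at 0.0909, GTT2 at 0.0355, RPS29A at -0.0296, TEF4 at 0.0089, TIF4631 at 0.0189, FUN12 at 0.0401, SCP160 at 0.0347, HEK2 at 0.0519, AMN1 at 0.0241, SUN4 at 0.0339, BAR1 at 0.037, STE6 at 0.0214, SPO11 at 0.044, SAH1 at 0.0469, SAM2 at 0.0566, MET6 at 0.0382, SSC1 at 0.0421, SSE1 at 0.0124, OPI3 at 0.0209, ADH1 at 0.0064, HXT4 at 0.048, HXT5 at 0.0434, HXT2 at 0.0044, HHF2 at -0.00704, HHT2 at -0.0042, NCE102 at -0.023, MET17 at 0.022, PRM10 at -0.0222, STE12 at 0.0255, CYC7 at -0.0227 and SPI1 at -0.085.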

Other observations

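The lists and genes in this part were chosen after the results were seen. All 6 measured aryl-alcohol dehydrogenase genes were lower in the knockout, from AAD4 at -0.252 to AAD6 at -0.758, with a median of -0.492. These genes resemble each other, so the rows may not be independent. The old yellow enzyme genes OYE2 at -0.272 and OYE3 at -0.330, which encode NADPH oxidoreductases, and GTT2 at -0.545 also fell. A hypothesis was that oxidant defence genes are lower as a group. The AAD genes, GTT2, OYE2 and OYE3 were left out of the list, and the prediction was written before its median and test were computed. One member, TRX2, also stands in the stress-induced list, which had been tested by then. Of its 15 genes 11 fell and 1 rose, with a median of -0.166 and GSH1 at -0.417, ATR1 at -0.350, YCF1 at -0.268 and AHP1 at -0.250 the lowest. Camera gave p = 2.7e-05 with the preset correlation and p = 0.102 with an estimated correlation. YAP1, the gene of the main transcription factor of this response, had 0.0318 and did not pass. The result is in line with a lower expression of the group, and the hypothesis does not say through which factor.

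Serine and glycine use and riboflavin synthesis each held several members that rose, CHA1 and RIB4 among them. GCV1 at 0.542, GCV3 at 0.523, GCV2 at 0.224 and SHM2 at 0.281 rose, while LPD1, a subunit shared with other dehydrogenases, fell by 0.205 and GLY1 fell by 0.0988, so that 5 of 9 members rose and 2 fell. In riboflavin synthesis 4 of 6 rose, RIB4, RIB5 at 0.383, RIB3 at 0.188 and RIB7 at 0.128, and RIB1 fell by 0.0957. Camera gave p = 0.0119 for the first list and p = 0.019 for the second, and p = 0.131 and 0.0955 with an estimated correlation. Both lists hold the genes that prompted them, so these p values are too small.

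Of 55 pairs of ribosomal protein paralogs, both members rose in 21 and 1 member alone in 12. The ratios of the 2 members differed in 5 pairs by limma on the difference, with the A copy above the B copy in all 5. The widest gaps were between RPL43A at 0.247 and RPL43B at -0.0875, between RPS27A at 0.264 and RPS27B at 0.0033, and between RPS22A at 0.0306 and RPS22B at -0.176. The other 2 pairs were RPS29A and RPS29B, and RPL9A and RPL9B. Shared probe signal would shrink such gaps, and probe sequences were not used here.

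Of all 6205 rows tested, 5127 had a symbol other than the ID. A rise of at least 0.5 log units past the threshold was seen in 5 rows. Of 36 rows that fell by as much, 21 had no symbol in the gene table, and rows of near-identical copies may share signal. Among them are the rows YFL-TYA at -0.644 ± 0.0707 and YFL-TYB at -0.679 ± 0.0532 (SD, n = 4), whose IDs are used as the table gives them. The row YNL337W had 0.717, 0.0751, 0.257 and 0.678 on arrays 1 to 4, so its mean of 0.432 passed the threshold with a spread of 0.316.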
